A study of Mus musculus with 3 samples.

How the data were processed

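Gene expression was measured in the liver of mice aged 16 weeks by sequencing total RNA depleted of ribosomal RNA. There were 3 libraries, 1 for each of 3 groups. They came from Ercc1-mutant mice fed ad libitum (Ercc1 AL), Ercc1-mutant mice under diet restriction (Ercc1 DR) and wild-type mice fed ad libitum (wt AL), on a mixed C57BL6J and FVB background. The labels do not say whether a library holds RNA of 1 animal or of several, nor the sex of the animals or the time of day at which livers were taken. The library titles, by which the libraries were assigned to groups, name genotype and diet. With 1 library per group there is no spread between animals, so no test between groups was made and no p-value or SD is given.

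The deposited values are FPKM, fragments per kilobase of transcript and M mapped fragments, 1 table of 23850 rows per library, and per the file headers each FPKM comes with a lower bound, an upper bound and a status code. The reads were placed on the mouse genome build mm10, per the submitters' processing notes. The tool that computed the values, its version and the gene annotation behind it are not given in the sources used here. The kit was a TruSeq protocol on RNA treated to remove ribosomal RNA, per the labels' protocols, and strand use in counting is not given, so a gene and its antisense partner are not separated. Rows with the status HIDATA or FAIL hold 0 in place of an estimate and were treated as missing. There were 59 HIDATA and 3 FAIL rows in wt AL, 91 and 5 in Ercc1 AL and 55 and 1 in Ercc1 DR, 97 rows in at least 1 library. Albumin and several major urinary protein genes were among them, so the most abundant transcripts are partly missing. Symbols repeated in 494 rows, and of repeated symbols the row with the highest mean FPKM was used for lists. Small RNA genes made up 839 rows and reached very large FPKM values, since their transcripts are short.

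The tables hold no counts. The deposited intervals allow a rough estimate of depth, if their widths are assumed to follow those of whole-number counts. Taking each bound as 2 SD from the midpoint, the fragments implied over all rows with an estimate came to 19.0 M in wt AL, 25.1 M in Ercc1 AL and 25.04 M in Ercc1 DR. The deposited interval reached 13.2%, 12.0% and 12.4% of the value to either side, in that order, for the median gene between 1 and 2 FPKM and 2.15%, 2.05% and 2.12% between 100 and 200 FPKM. Those percentages are over genes with 1 transcription start entry and a positive lower bound, without small RNA genes. These intervals cover counting and assignment of fragments in 1 library and not the difference between animals. The deposited FPKM lay outside its own interval in 9.70%, 12.9% and 13.0% of rows, and the midpoint of the interval was tried in its place. Genes named below are among these rows. In Ercc1 AL, Lcn2 was at 19.1 FPKM with an interval of 13.9 to 16.2, and Mup20 at 3205 FPKM with 2470 to 2496. Others lay inside, such as Gpcpd1 at 16.2 FPKM with 15.7 to 16.9.

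Each pair of libraries was compared by the log2 ratio of FPKM + 1 over genes with an FPKM of at least 1 in either library, and genes with at least a 2-fold ratio on that scale were counted. The pseudocount of 1 understates the ratio of low genes. The libraries differ in their general level, so each comparison was also rescaled to a median log2 FPKM ratio of 0 over the 9109 genes with at least 1 FPKM in all 3 libraries, and log2 ratios of single genes in the text are after this rescaling unless called as deposited. Official symbols were those left without predicted or clone-based models, small RNA genes, pseudogenes and immunoglobulin or T cell receptor segments.

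The genes named were fixed by a rule before the data were examined. It takes Ercc1, then the 10 genes with the highest and the 10 with the lowest log2 ratio as deposited in each comparison among official symbols with at least 5 FPKM in either library, then from each list described the 2 to 4 members with the largest absolute ratio, and the sex chromosome genes. Some genes that the rule takes are not described here. Other genes named in the text were chosen after their values were seen. Before the data were examined, 26 gene lists and 10 lists of cell type markers were also fixed. Lists of amino acid breakdown and urea cycle genes and of major urinary protein genes were added afterwards. The median log2 ratio of a list with at least 3 measured genes was set against 10000 random lists of the same size, each gene replaced by 1 of its 100 neighbours in mean expression. A list stood apart when its median lay outside the central 95% of these random lists, which describes these libraries and is no test between conditions. Lists for mitochondrially encoded genes, for T, B and NK cells and for adipocytes had too few measured members for this.

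Gene length was the span from start to end in the deposited tables, and its relation with the log2 ratio was Spearman's rho across genes, which are not independent replicates. Coordinates are those of the tables in mm10, counted from 1. The reference annotation used for exon overlaps and exonic lengths was GENCODE M21, on the same build. For each gene with at least a 2-fold range over the libraries, the library farthest from the middle value was recorded as the one standing apart, with an exact 95% binomial interval on its share. Alternatives were other pseudocounts, filters, scalings and fold thresholds, official symbols, exonic length, genes of at least 1 kb, partial correlation and matching on length, and after the data were examined the midpoint of the interval, rows with the status OK, and combinations of these.

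The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1. The steps were tested on simulated libraries with the levels of wt AL, normal noise on the log2 scale that was chosen and not estimated from these data, and 50 genes well above the filter changed for each fold size. For Ercc1 AL against wt AL, over 10888 genes, the 2-fold threshold recovered 94% of genes changed 2.5-fold and 100% of those changed 4-fold. For Ercc1 DR against Ercc1 AL, over 10892 genes, it recovered 90% and 100%. For Ercc1 DR against wt AL, over 10892 genes, it recovered 96% and 100%. Of 100 simulated random lists with no change, 9, 4 and 7 stood apart in these 3 comparisons.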

Results

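Liver RNA was compared between 3 mouse libraries at 16 weeks of age, 1 each for Ercc1-mutant mice fed ad libitum (Ercc1 AL), Ercc1-mutant mice under diet restriction (Ercc1 DR) and wild-type mice fed ad libitum (wt AL). The mutants carry a null Ercc1 allele and a second mutant allele. ERCC1 pairs with XPF, the product of Ercc4, in an endonuclease of nucleotide excision repair and crosslink repair. Diet restriction lowers food intake. The comparisons follow from the design and ask how genotype goes with liver expression under free feeding, how diet does within the mutant, and how the restricted mutant stands to the freely fed wild type. Every value is of 1 library per group, so a difference between libraries has no replicate check, and p-values and SDs are not given. The fragments implied by the deposited intervals were 19.0 M in wt AL, 25.1 M in Ercc1 AL and 25.04 M in Ercc1 DR. Genes with an FPKM of at least 1 numbered 10436, 11861 and 10887 in that order, and genes with at least 5 FPKM numbered 3294, 4147 and 4863.

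The targeted gene, Ercc1, lies on chromosome 7 from 19345071 to 19356524 on the plus strand of mm10 and shares exonic sequence with the antisense gene Cd3eap. Its FPKM was 0.461 in wt AL, with a deposited interval of 0.283 to 0.630, 0.573 in Ercc1 AL (0.377 to 0.720) and 0.475 in Ercc1 DR (0.29998 to 0.634). The intervals overlapped, and a value summed over the whole gene does not separate mutant from intact transcripts, so Ercc1 does not check the labels. Its partner Ercc4 stood at 0.829, 0.985 and 1.01 FPKM. The Y-linked genes Ddx3y (3.81, 6.50 and 11.2 FPKM in wt AL, Ercc1 AL and Ercc1 DR) and Eif2s3y (4.49, 8.60 and 19.5 FPKM) were measured in every library. The other Y-linked genes were lower, with Kdm5d at 1.05, 1.44 and 1.02 FPKM and Uty at 0.662, 1.22 and 1.64 FPKM. Xist, transcribed from the inactive X chromosome, was at 0.646, 0.857 and 0.437 FPKM.

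In Ercc1 AL against wt AL, lipogenic genes were lower, male-biased liver genes and several acute phase genes were higher, and ribosomal protein genes were high relative to matched lists. Scd1, the stearoyl-CoA desaturase (chromosome 19, 44394450 to 44407709), stood at 88.7 FPKM against 441 FPKM in wt AL, a log2 ratio of -2.79 after median rescaling. Lcn2, an iron-binding acute phase protein (chromosome 2, 32384637 to 32387739), was at 19.1 against 0.959 FPKM, a log2 ratio of 2.997. Mup20, a male urinary protein also called darcin (chromosome 4, 62050235 to 62054117), was at 3205 against 368 FPKM, and Cyp7b1, an oxysterol hydroxylase of bile acid synthesis, at 61.0 against 6.42 FPKM. The p53 targets Ccng1, Phlda3 and Eda2r were higher, with log2 ratios of 1.46, 1.42 and 1.03.

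Of 12359 genes measured in this comparison, 717 were at least 2-fold higher and 272 at least 2-fold lower in Ercc1 AL as deposited. Their median log2 ratio was 0.34, and over the 9109 genes with at least 1 FPKM in all libraries the median was 0.49. After rescaling to the latter, 291 genes were higher and 605 lower. The share of higher genes among those past the threshold thus went from 72.5% to 32.5%. With official symbols only, 386 genes were higher and 186 lower as deposited, and scaled to the sum without the 100 most abundant genes 207 were higher and 877 lower. The genes with the highest ratios after Lcn2, Mup20 and Cyp7b1 were Tnp1 (2.65 to 25.3 FPKM), a spermatid protein, Amd1 (0.453 to 6.45 FPKM), Saa2 (16.1 to 84.2 FPKM), Selenbp2 (10.3 to 55.0 FPKM), Arhgap25 (1.68 to 11.3 FPKM), Gpcpd1 (2.88 to 16.2 FPKM) and Ugt2b1 (21.4 to 94.98 FPKM). Amd1 is uncertain, because its near-copy Amd2 could share reads with it, which was not measured. The genes with the lowest ratios were Csn1s2a (43.0 to 2.96 FPKM), a milk casein, Csad (16.2 to 1.44 FPKM), which makes taurine precursors and overlaps the antisense gene Zfp740, Cyp2c29 (52.2 to 7.19 FPKM), Hist2h4 (34.7 to 4.59 FPKM), Cartpt (14.4 to 1.69 FPKM), Trim50 (9.64 to 0.928 FPKM), Cish (9.73 to 0.981 FPKM), Efcab10 (7.61 to 0.745 FPKM), Scd1 and Adam33 (13.6 to 1.959 FPKM).

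Of 19 fatty acid synthesis genes, 7 were at least 2-fold lower, none higher and 12 within the threshold in Ercc1 AL as deposited, and 11 were lower after rescaling. The list's median was 1.13 below that of matched random lists on the log2 scale, below all 10000 of them (percentile 0). Besides Scd1, malic enzyme Me1 had a log2 ratio of -2.08, Thrsp, a regulator of lipogenesis, -2.03 and acetyl-CoA synthetase Acss2 -1.82. Cholesterol synthesis genes did not stand apart (24 genes, median -0.12 from matched lists, percentile 9.90), and within them Sc4mol had a log2 ratio of 0.85 and Fdps one of -1.44. Fatty acid oxidation genes did not stand apart either (-0.10, percentile 22.9), with Cpt1a, which admits fatty acids to mitochondria, at 0.85 and Acaa1b at -1.59.

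Male-biased liver genes had 9 members higher and 3 lower of 14 as deposited, 7 and 3 after rescaling, and a median 0.85 above matched lists (percentile 100). Mup20, Cyp7b1 and Selenbp2 were the highest, while Cyp4a12a (33.4 to 9.82 FPKM) was lower. Female-biased genes had 2 members higher and 3 lower of 12 as deposited, none higher and 4 lower after rescaling, and a median 0.34 below matched lists (percentile 1.80, apart in 9 of 11 alternative settings). Among them Cyp2b9 (5.47 to 0.444 FPKM) had a log2 ratio of -2.45. Of growth hormone and IGF1 axis genes, Cish, a feedback inhibitor of cytokine receptor signalling, had a log2 ratio of -2.78, while the list of 13 did not stand apart (median -0.19 from matched lists, percentile 8.67). Irs1, an insulin receptor substrate in that list, was at 0.29. The sex chromosome genes did not stand apart (percentile 88.2).

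The p53 target list had 5 of 19 members higher and none lower as deposited, 3 higher and 1 lower after rescaling, and a median 0.21 above matched lists (percentile 98.7). Cdkn1a, the cell cycle inhibitor p21, was at 16.3 against 6.72 FPKM, a log2 ratio of 0.72. Acute phase genes had 6 of 23 members higher and none lower as deposited, 5 and none after rescaling, and their median lay inside the central 95% of matched lists (0.24, percentile 95.6), as it did in 8 of 11 alternative settings. In this list the metallothionein gene Mt1 (20.3 to 87.9 FPKM) and Saa1 (54.2 to 171 FPKM) had log2 ratios of 1.59 and 1.15 beside Lcn2 and Saa2. Interferon response genes stood 0.17 below matched lists (22 genes, percentile 1.86), with none past 2-fold, Bst2 at 0.50 and Mx2 at -0.97. This list stood apart in only 4 of 11 alternative settings and turned to 0.31 at an FPKM of at least 5. In the unfolded protein response list, chaperone genes Dnajb9 (3.84 to 17.7 FPKM) and Hspa5 (53.9 to 138 FPKM) had log2 ratios of 1.52 and 0.85, and the list did not stand apart (0.20, percentile 92.8).

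Ribosomal protein genes were above the median of the measured genes in 66 of 69 cases, and their median was 0.39 above matched lists (percentile 100). As deposited 20 of them were at least 2-fold higher and none lower, and after rescaling 1 was higher. Rps27 went from 34.8 to 99.96 FPKM and Rps10 from 24.96 to 66.8 FPKM. Replication-dependent histone genes had 9 of 60 members lower and none higher as deposited, 16 lower after rescaling, and a median 0.70 below matched lists (percentile 0). The H4 genes Hist1h4d (141 to 33.7 FPKM) and Hist1h4c (35.7 to 10.2 FPKM) followed Hist2h4, and such near-identical genes can share reads. Circadian clock genes stood 0.25 below matched lists (20 genes, percentile 0.530), with Clock at -1.52 and Usp2 at 0.89, and did so in 7 of 11 alternative settings. Of lists added after the data were examined, 32 amino acid breakdown and urea cycle genes were 0.38 above matched lists (percentile 99.96), with 10 higher as deposited and 2 after rescaling, and 12 major urinary protein genes were 0.89 above (percentile 99.9), with 11 higher as deposited and 5 after rescaling. The aminotransferase Agxt (5.41 to 21.8 FPKM) led the former. Other lists did not stand apart, namely NRF2 and glutathione (0.14), gluconeogenesis (0.09), bile acids (0.21), xenobiotic metabolism (0.09), heat shock (0.15), nucleotide excision repair (0.08), cell cycle (0.08), senescence (0.01), autophagy and lysosome (0.11), oxidative phosphorylation (-0.09) and abundant noncoding RNA (-0.32). Lists overlap, since Cyp7b1 and Slco1a1 are in both the male-biased and the bile acid list, and Got1, Gpt, Tat and Sds in both the gluconeogenesis and the amino acid list.

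Of cell type markers in this comparison, endothelial genes were 0.36 below matched lists (14 genes, percentile 0.260), neutrophil genes 0.71 below (4 genes, percentile 0.230, apart in 8 of 10 alternative settings), cholangiocyte genes 0.69 below (4 genes, percentile 0.110) and erythroid genes 0.71 below (5 genes, percentile 1.06). As deposited none of these markers was at least 2-fold lower, and after rescaling 1 endothelial, 2 neutrophil, 1 cholangiocyte and 1 erythroid gene were. Gpr182, an endothelial receptor, was at 5.29 against 10.5 FPKM, the neutrophil peroxidase Mpo at 3.50 against 6.41 FPKM, and the bile duct keratin Krt7 at 0.807 against 2.37 FPKM. The erythroid list was mixed, with Alas2, the erythroid heme synthesis enzyme, at 14.8 against 3.10 FPKM and the globin Hba-a2 at 72.3 against 145 FPKM. Hepatocyte (percentile 66.2), macrophage (45.4), stellate cell (45.3) and pancreatic (22.3) markers did not stand apart. Olfactory and vomeronasal receptor genes, which liver does not use, had a median log2 FPKM ratio of 0.48 (1428 genes, bootstrap 95% interval 0.43 to 0.52), beside 0.49 for the genes with at least 1 FPKM in all libraries. This set of receptor genes was chosen after the data were examined. Its bootstrap interval, here and below, is over genes within 1 pair of libraries and does not cover the difference between animals.

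**Figure D1:**
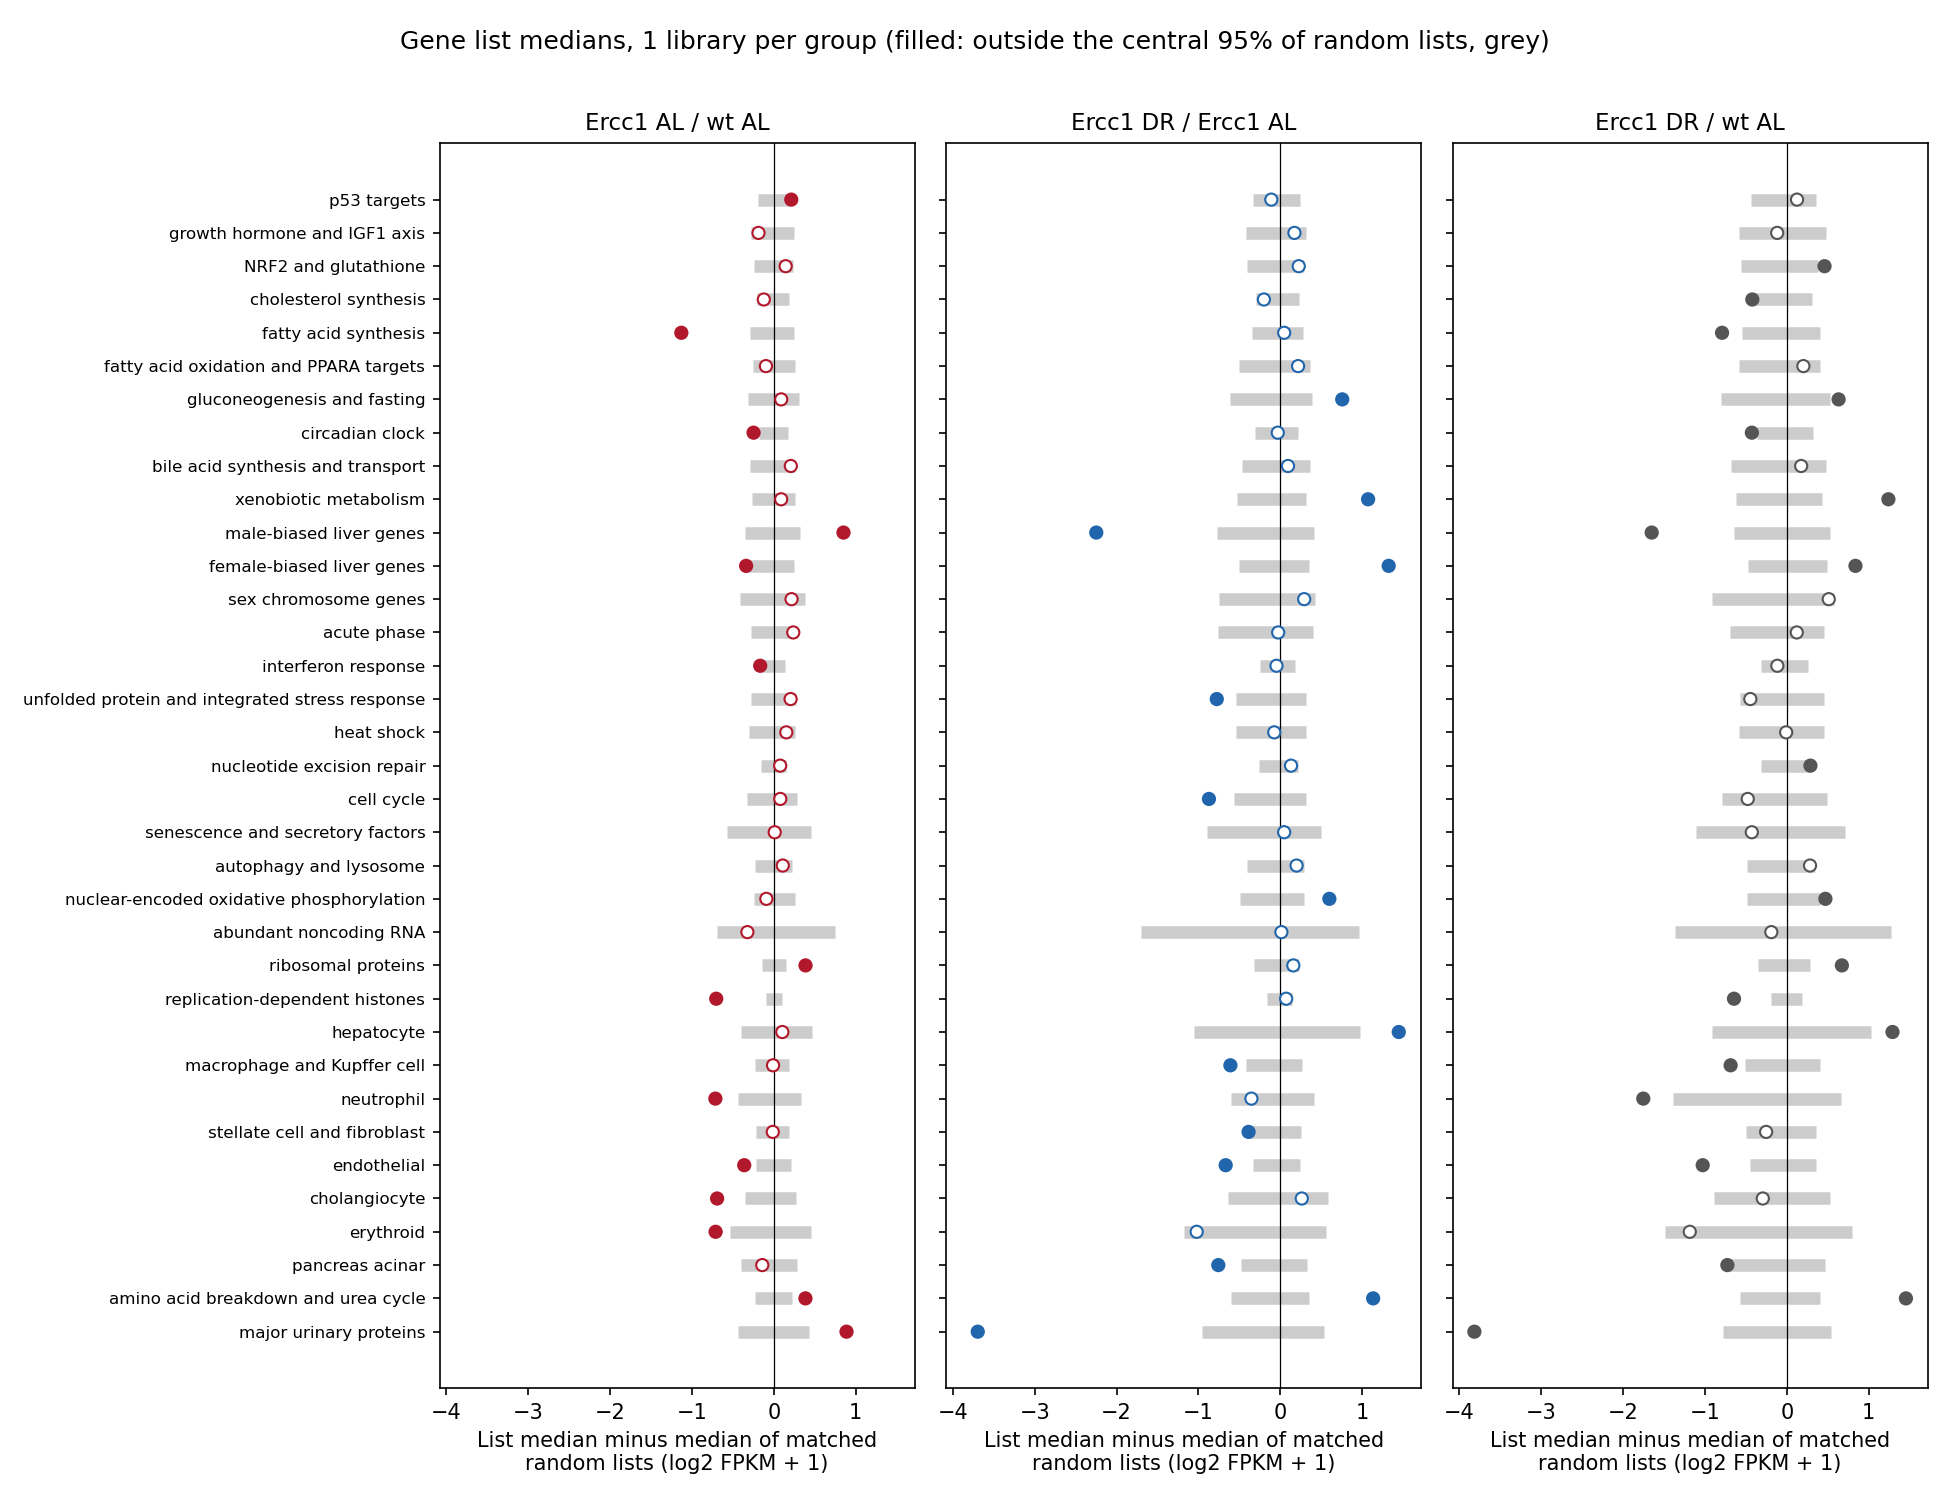
Median log2 ratio of each gene list minus the median of its matched random lists (x axis) for the 3 comparisons, with 1 library per group. Grey bars span the central 95% of 10000 random lists and filled points lie outside it, as for fatty acid synthesis at -1.13 in Ercc1 AL against wt AL and male-biased genes at -2.25 in Ercc1 DR against Ercc1 AL.

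In Ercc1 DR against Ercc1 AL, female-biased, xenobiotic and amino acid breakdown genes and several members of the gluconeogenesis and fasting list were higher. Male-biased genes, major urinary protein genes and serum amyloid genes were lower. Lepr, the leptin receptor (chromosome 4, 101717407 to 101815354), was at 53.03 FPKM in Ercc1 DR and 1.34 FPKM in Ercc1 AL, a log2 ratio of 4.27 after median rescaling. Mup13 (chromosome 4, 61224307 to 61228286) was at 25.8 against 837 FPKM, a log2 ratio of -5.29, and Saa2, a serum amyloid of the acute phase (chromosome 7, 46751833 to 46754314), at 3.50 against 84.2 FPKM, a log2 ratio of -4.54. Got1, the cytosolic aspartate aminotransferase, was at 470 against 41.0 FPKM.

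Of 12361 genes measured in this comparison, 803 were at least 2-fold higher and 1077 at least 2-fold lower in Ercc1 DR as deposited. Their median log2 ratio was 0.17, against 0.33 over the 9109 genes with at least 1 FPKM in all libraries. After rescaling to the latter, 386 genes were higher and 1479 lower, so the share of higher genes went from 42.7% to 20.7%. With official symbols only, 736 genes were higher and 489 lower as deposited. Scaled to the sum without the 100 most abundant genes 6367 were higher and 209 lower, so the direction of the majority depends on the scaling. That sum still includes most of the 839 rows of small RNA genes, so it also follows their level. Also among the genes with the highest ratios were the cytochrome P450 genes Cyp2c39 (3.33 to 129 FPKM), Cyp2c38 (1.13 to 40.1 FPKM), Cyp4a14 (10.6 to 138 FPKM), Cyp2b9 (0.444 to 16.1 FPKM) and Cyp3a41a (4.55 to 62.2 FPKM), the estrogen sulfotransferase Sult1e1 (0.905 to 30.1 FPKM), Agxt2l1 (4.75 to 91.4 FPKM) and the organic anion transporter Slco1a4 (3.60 to 56.9 FPKM). The other genes with the lowest ratios were Mup12 (1148 to 36.5 FPKM), Mup8 (941 to 30.3 FPKM), Mup9 (1018 to 43.2 FPKM), Mup6 (193 to 11.1 FPKM), Mup5 (280 to 23.3 FPKM), Mup16 (11.4 to 0.0717 FPKM), Saa1 (171 to 8.94 FPKM) and Lce3a (128 to 9.72 FPKM), a gene of the skin barrier. The major urinary protein genes are near-identical copies, so single members are uncertain. As a group added after the data were examined, all 12 of those measured were lower, with a median 3.70 below matched lists (percentile 0).

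Male-biased liver genes had 10 of 13 members lower and none higher as deposited, 12 lower after rescaling, and a median 2.25 below matched lists (percentile 0). Among them were Hsd3b5, a steroid reductase (10.5 to 0.166 FPKM), the fatty acid elongase Elovl3 (11.6 to 0.304 FPKM) and Cyp4a12a (9.82 to 0.462 FPKM). Female-biased genes had 11 of 16 members higher and none lower, 10 higher after rescaling, and a median 1.32 above matched lists (percentile 100). Among them Cyp2b9, Cyp3a41a and Cyp3a16 had log2 ratios of 3.36, 3.21 and 2.78. The sex chromosome genes did not stand apart (percentile 91.3), with Eif2s3y and Ddx3y at log2 ratios of 0.78 and 0.41, Uty at 0.06, Kdm5d at -0.45 and Xist at -0.50. Growth hormone and IGF1 axis genes went both ways and did not stand apart (0.17, percentile 83.7). Dio1, a thyroid hormone deiodinase, was at 0.755 against 11.2 FPKM and Bcl6, a repressor, at 1.35 against 5.56 FPKM, while Socs2 and Cish had log2 ratios of 1.29 and 1.36.

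Xenobiotic metabolism genes had 16 of 22 members higher and none lower, 14 higher and 1 lower after rescaling, and a median 1.07 above matched lists (percentile 100). Cyp3a11 went from 77.2 to 716 FPKM, Cyp2c37 from 12.6 to 88.4 FPKM and Cyp2c29 from 7.19 to 41.7 FPKM. Gluconeogenesis and fasting genes had 8 of 15 members higher and none lower, 6 higher after rescaling, and a median 0.76 above matched lists (percentile 99.98). Beside Got1 these included the serine dehydratase Sds (14.3 to 112 FPKM) and Igfbp1, a fasting-responsive IGF binding protein (5.70 to 39.3 FPKM). Pck1 (194 to 234 FPKM) and G6pc (22.5 to 19.3 FPKM), of the same list, were not past the threshold. Of 32 amino acid breakdown and urea cycle genes, a list added after the data were examined, 24 were higher and none lower, 19 higher after rescaling, and the median was 1.13 above matched lists (percentile 100). The mitochondrial glutamate carrier Slc25a22 went from 5.93 to 65.0 FPKM and the cystathionine lyase Cth from 33.2 to 225 FPKM.

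Nuclear-encoded oxidative phosphorylation genes had 18 of 27 members higher and none lower as deposited, 6 after rescaling, and a median 0.60 above matched lists (percentile 99.99). Uqcrc2 and Atp5c1 had log2 ratios of 1.56 and 1.29. The NRF2 and glutathione list had 7 of 18 members higher and none lower, before and after rescaling, without standing apart (0.22, percentile 93.9), and the glutathione transferases Gsta2 and Gsta1 led it at 2.34 and 2.14. Fatty acid oxidation genes did not stand apart (0.22, percentile 87.5), with Cyp4a14 at 3.26 and Cyp4a10 at 2.33. Nor did fatty acid synthesis genes (0.05, percentile 63.0), in which Scd1 went from 88.7 to 325 FPKM and Acly, the citrate lyase, had a log2 ratio of 1.15. The acute phase list went both ways (-0.03, percentile 47.5), with Saa2 and Saa1 low and the metallothioneins Mt2 (172 to 991 FPKM) and Mt1 (87.9 to 347 FPKM) high.

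Unfolded protein response genes stood 0.78 below matched lists (15 genes, percentile 0.470), with 1 past 2-fold as deposited and 2 after rescaling, all lower. Creld2 and Hyou1, which act in the endoplasmic reticulum, had log2 ratios of -1.84 and -1.30. Cell cycle genes had 4 of 8 measured members lower and none higher, and a median 0.87 below matched lists (percentile 0.280). The replication helicase genes Mcm2 (5.28 to 1.51 FPKM), Mcm6 (4.68 to 1.28 FPKM) and Mcm7 (12.6 to 5.65 FPKM) were lower. Pcna, at 11.1 against 5.79 FPKM, was not past the 2-fold threshold. That list stood apart in 7 of 11 alternative settings and turned to 0.068 with no filter on low values. The p53 targets did not stand apart (-0.11, percentile 20.5), with Sesn1 (1.65 to 7.32 FPKM) higher and Phlda3 (3.22 to 0.984 FPKM) and Eda2r (3.36 to 1.18 FPKM) lower. Other lists did not stand apart, namely cholesterol synthesis (-0.20), circadian clock (-0.03), bile acids (0.09), interferon response (-0.05), heat shock (-0.08), nucleotide excision repair (0.13), senescence (0.05), autophagy and lysosome (0.20), abundant noncoding RNA (0.01), ribosomal proteins (0.16) and histones (0.07). Cyp7b1, of the bile acid list, had a log2 ratio of -2.63, and the lysosomal protease Ctsl (39.5 to 200 FPKM), of the autophagy list, one of 1.98.

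Several lists of cell type markers also stood apart in this comparison. Hepatocyte markers were all above the median of the measured genes, 17 of 17, and their median was 1.45 above matched lists (percentile 99.98), of whose neighbours at such levels 52.7% are small RNA genes and 1.94% major urinary protein genes. As deposited 7 of 17 were at least 2-fold higher and 5 after rescaling, and the list stood apart in 9 of 11 alternative settings, with an excess of 0.23 and no longer apart with official symbols. The urea cycle genes Cps1 (299 to 1146 FPKM) and Arg1 (169 to 626 FPKM) led. Endothelial markers were 0.67 below matched lists (14 genes, percentile 0.0100), macrophage markers 0.61 below (13 genes, percentile 0.220, with 1 at least 2-fold higher and none lower as deposited and 1 each after rescaling), stellate cell markers 0.39 below (12 genes, percentile 2.03, apart in only 5 of 10 alternative settings) and pancreatic markers 0.76 below (6 genes, percentile 0.280). Of the endothelial markers 2 were at least 2-fold lower under either scaling, of the stellate cell markers none, and of the pancreatic markers none as deposited and 2 after rescaling. Oit3, of liver sinusoidal endothelium, was at 4.84 against 15.2 FPKM, C1qa, a complement gene of macrophages, at 2.38 against 4.72 FPKM, the collagen Col1a2 at 1.49 against 2.51 FPKM and Ctrb1, a digestive protease, at 0.958 against 2.81 FPKM. The background over silent receptor genes moved the same way, with a median log2 FPKM ratio of -1.001 (1428 genes, interval -1.03 to -0.97), 96.9% of them lower in Ercc1 DR, at a median of 0.0901 against 0.180 FPKM. Neutrophil (percentile 10.6), erythroid (4.07) and cholangiocyte (73.8) markers did not stand apart, the erythroid list in 8 of 11 alternative settings.

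**Figure D2:**
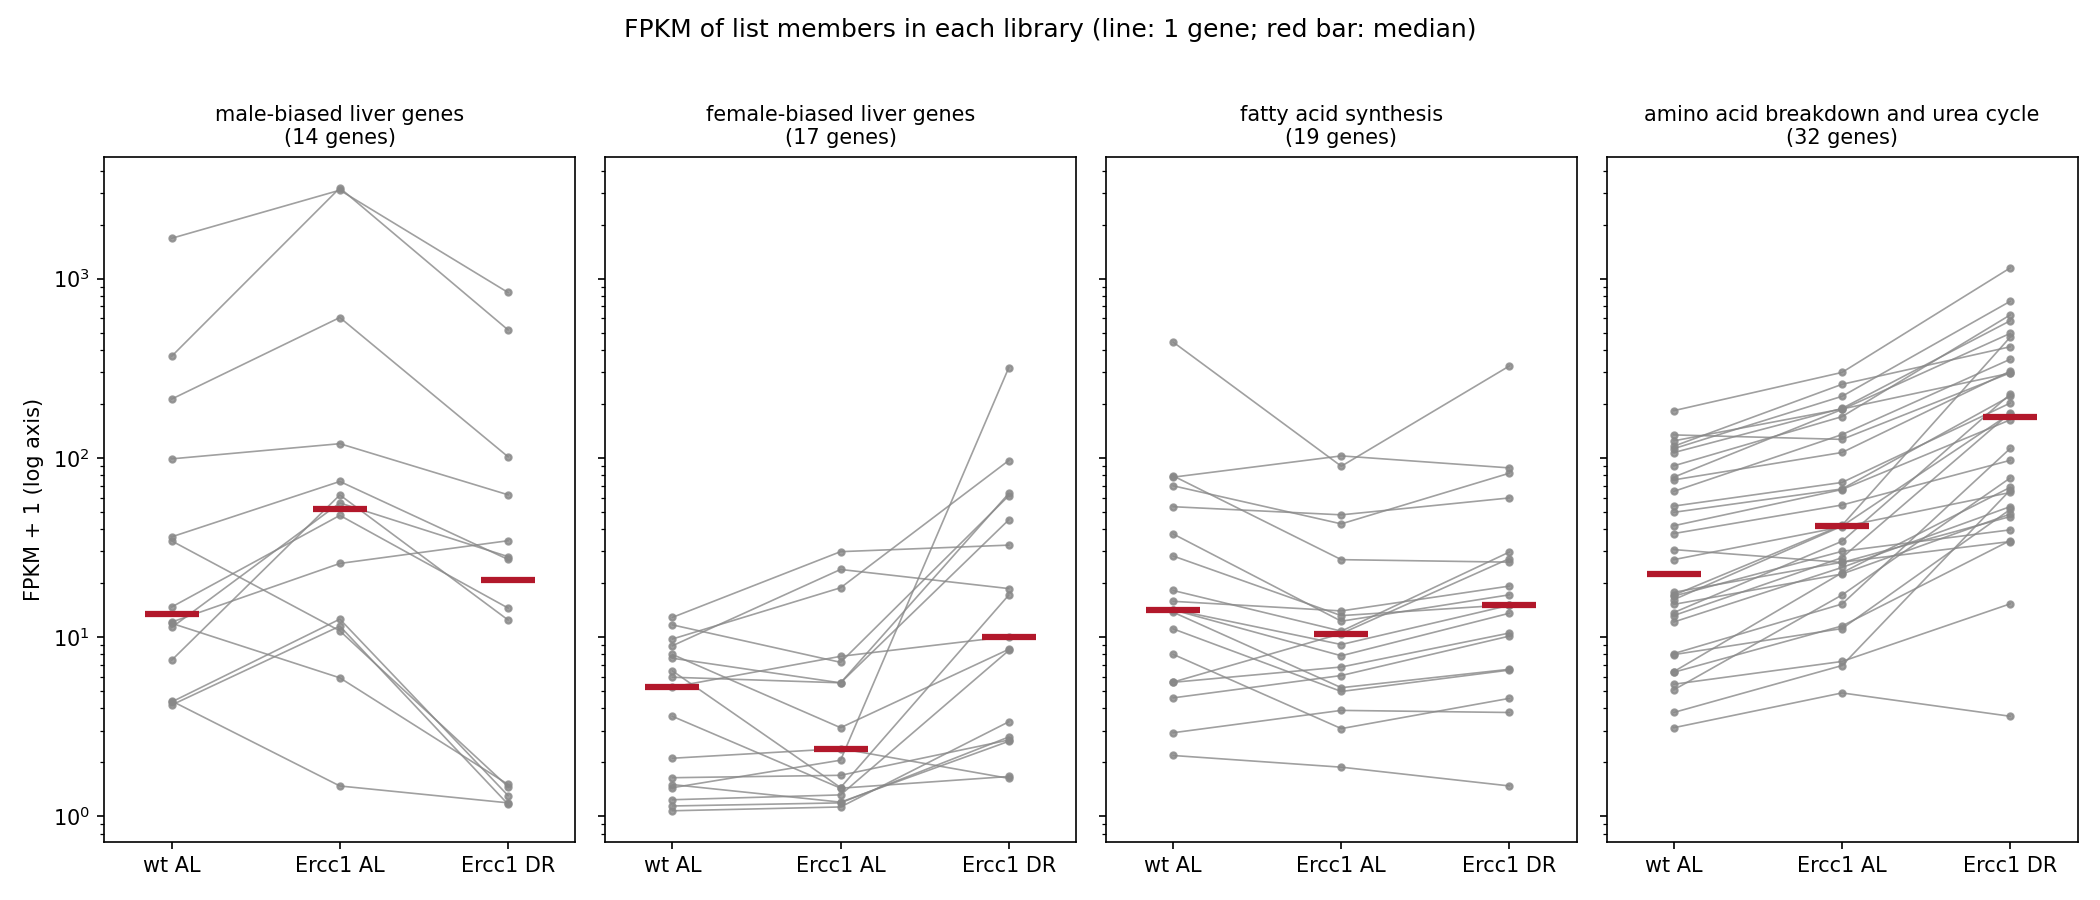
FPKM + 1 on a log axis (y axis) of the members of 4 gene lists in each of the 3 libraries, with 1 line per gene and a red bar at the median. Members of a list differ in their course, and as examples the male-biased gene Elovl3 is at 11.6 FPKM in Ercc1 AL and 0.304 FPKM in Ercc1 DR, and the amino acid breakdown gene Cth at 225 FPKM in Ercc1 DR.

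In Ercc1 DR against wt AL, which differ in both genotype and diet, amino acid breakdown, xenobiotic and metallothionein genes were higher and male-biased genes were lower. Relative to matched lists, oxidative phosphorylation and ribosomal protein genes were high and endothelial and fatty acid synthesis genes low. Got1 (chromosome 19, 43499753 to 43524605) was at 470 against 16.1 FPKM, a log2 ratio of 4.02. Mt2, a metal-binding metallothionein (chromosome 8, 94172618 to 94173567), was at 991 against 55.1 FPKM. Cyp4a12a, a male-biased fatty acid hydroxylase (chromosome 4, 115299046 to 115332815), was at 0.462 against 33.4 FPKM, a log2 ratio of -5.05.

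Of 12127 genes measured in this comparison, 2916 were at least 2-fold higher and 1047 at least 2-fold lower in Ercc1 DR as deposited. The median log2 ratio of these genes was 0.50, and that of the 9109 genes with at least 1 FPKM in all libraries 0.78. After rescaling to the latter, 730 genes were higher and 1997 lower, so the share of higher genes went from 73.6% to 26.8%. With official symbols only, 2660 genes were higher and 627 lower as deposited, and scaled to the sum without the 100 most abundant genes 4946 were higher and 686 lower. Also among the genes with the highest ratios were Fam134b, a receptor of endoplasmic reticulum autophagy (2.20 to 115 FPKM), Lepr (0.738 to 53.03 FPKM), Sult1e1 (0.0955 to 30.1 FPKM), Gpcpd1 (2.88 to 77.3 FPKM), Slco1a4 (2.06 to 56.9 FPKM), Slc25a22 (2.79 to 65.0 FPKM) and Cth (12.7 to 225 FPKM). The other genes with the lowest ratios were Csn1s2a (43.0 to 0.563 FPKM), Cartpt (14.4 to 0.439 FPKM) and Mup15, Mup13, Mup14, Mup12, Mup8, Mup7 and Mup1, whose log2 ratios ran from -4.69 to -4.25. Of these, Mup15, Mup14, Mup7 and Mup1 had no estimate in Ercc1 AL.

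Amino acid breakdown and urea cycle genes had 29 of 32 members higher and none lower as deposited, 22 higher after rescaling, and a median 1.45 above matched lists (percentile 100). The arginine transporter Slc7a2 had a log2 ratio of 3.22. Xenobiotic genes were 1.24 above matched lists (percentile 100), with 16 of 22 higher and none lower as deposited, 12 and 2 after rescaling, among them Fmo5 (20.6 to 189 FPKM) and Cyp2a5 (26.5 to 215 FPKM). Gluconeogenesis genes were 0.63 above (percentile 98.9), with 9 of 15 higher as deposited and 7 after rescaling, and Gpt2 at 1.67. Oxidative phosphorylation genes were 0.47 above (27 genes, percentile 98.7), all 27 above the median of the measured genes, 25 of them at least 2-fold higher as deposited and 8 after rescaling, with Ndufs3 at 1.40. Ribosomal protein genes were 0.67 above (70 genes, percentile 100), 58 of them at least 2-fold higher as deposited and 17 after rescaling, with Rps13 (30.8 to 180 FPKM) and Rpl39 (68.2 to 373 FPKM) the highest. The NRF2 and glutathione list was 0.46 above (percentile 99.3), with 13 of 18 higher as deposited and 7 after rescaling, among them Gstm3 (8.24 to 86.3 FPKM). This list and that of oxidative phosphorylation each stood apart in 9 of 11 alternative settings. Nucleotide excision repair genes were 0.29 above (20 genes, percentile 97.95), with 5 at least 2-fold higher as deposited and none after rescaling, and Rad23b and Xpa, a damage-binding protein, were each at 0.85. The repair list stood apart in only 4 of 11 alternative settings, and its excess was as low as 0.085.

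Male-biased genes had 9 of 16 members lower and 2 higher as deposited, 11 lower and none higher after rescaling, and a median 1.65 below matched lists (percentile 0). Female-biased genes had 11 of 17 higher and 1 lower as deposited, 7 and 1 after rescaling, and a median 0.84 above (percentile 99.95), with Cyp2a4 (8.74 to 95.6 FPKM) among them. Fatty acid synthesis genes were 0.79 below matched lists (percentile 0.660), with 3 of 19 members at least 2-fold lower and 2 higher as deposited, 7 and 1 after rescaling, Thrsp at -2.36, Me1 at -1.87 and Gpam, of triglyceride synthesis, at 1.59. Cholesterol synthesis genes were 0.42 below (percentile 1.71, apart in 7 of 11 alternative settings), with none of 23 lower and 3 higher as deposited, 4 lower and none higher after rescaling, and Fdps at -1.41. Circadian clock genes were 0.43 below (percentile 1.13), with none of 20 lower and 3 higher as deposited, 4 lower and 1 higher after rescaling, Npas2 at -1.36 and Usp2 at 1.73. Histone genes were 0.65 below (percentile 0), with 1 of 60 lower and 2 higher as deposited, 8 and 1 after rescaling, Hist2h3b at -1.84 and Hist1h1c at 1.66. The p53 targets did not stand apart (0.12, percentile 74.3), with Sesn1 at 1.68 and Cdkn1a at 1.32 (30.8 against 6.72 FPKM), nor did acute phase genes (0.12, percentile 68.4), with Saa1 at -3.20. Major urinary protein genes, added after the data were examined, were lower in 18 of 19 cases, with a median 3.82 below matched lists (percentile 0). Other lists did not stand apart, namely the growth hormone and IGF1 axis (-0.12), fatty acid oxidation (0.20), bile acids (0.17), sex chromosome genes (0.51), interferon response (-0.12), unfolded protein response (-0.45), heat shock (-0.01), cell cycle (-0.48), senescence (-0.43), autophagy and lysosome (0.28) and abundant noncoding RNA (-0.19).

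Endothelial markers were 1.03 below matched lists (percentile 0.0200), with 2 of 13 at least 2-fold lower as deposited and 7 after rescaling, macrophage markers 0.69 below (12 genes, percentile 0.840, with 1 higher and none lower as deposited and 1 each after rescaling), neutrophil markers 1.75 below (3 genes, percentile 1.26, apart in 8 of 10 and at -0.064 with no filter) and pancreatic markers 0.73 below (6 genes, percentile 2.29, apart in only 5 of 10 alternative settings and at -0.033 with no filter), while hepatocyte markers were 1.29 above (17 genes, percentile 99.7, apart in 9 of 11 and at 0.34, not apart, with official symbols). Gpr182 stood at 1.49 against 10.5 FPKM and Csf3r, of neutrophils, at 1.39 against 4.52 FPKM, while Arg1 was at 626 against 89.2 FPKM. The background over silent receptor genes had a median log2 FPKM ratio of -0.54 (interval -0.59 to -0.48). Stellate cell (percentile 12.2), cholangiocyte (34.8) and erythroid (9.86) markers did not stand apart, the erythroid list in 6 of 10 alternative settings.

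Gene length was examined because Ercc1 deficiency leaves DNA damage that can block transcription, which long genes meet more often. Across genes, Spearman's rho between gene span and log2 ratio was -0.060 for Ercc1 AL against wt AL, 0.155 for Ercc1 DR against Ercc1 AL and 0.1001 for Ercc1 DR against wt AL. With official symbols only the values were -0.039, 0.034 and 0.011. The shortest decile of all genes held 57.0% small RNA genes in the comparison of genotypes. In official symbols the longest decile began at 103 to 104 kb, depending on the comparison. Its median was 0.11 below that of all genes in Ercc1 AL against wt AL, 0.12 below in Ercc1 DR against Ercc1 AL and 0.23 below in Ercc1 DR against wt AL. The shortest decile of official symbols was also below, by 0.05, 0.15 and 0.25. Mean log2 expression was lowest in the longest decile, with medians of 1.51, 1.65 and 1.57. The pseudocount shrinks the ratios of low genes, so the deciles do not separate length from expression level. For Ercc1 AL against wt AL, rho became 0.067 with no filter on low values.

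**Figure D3:**
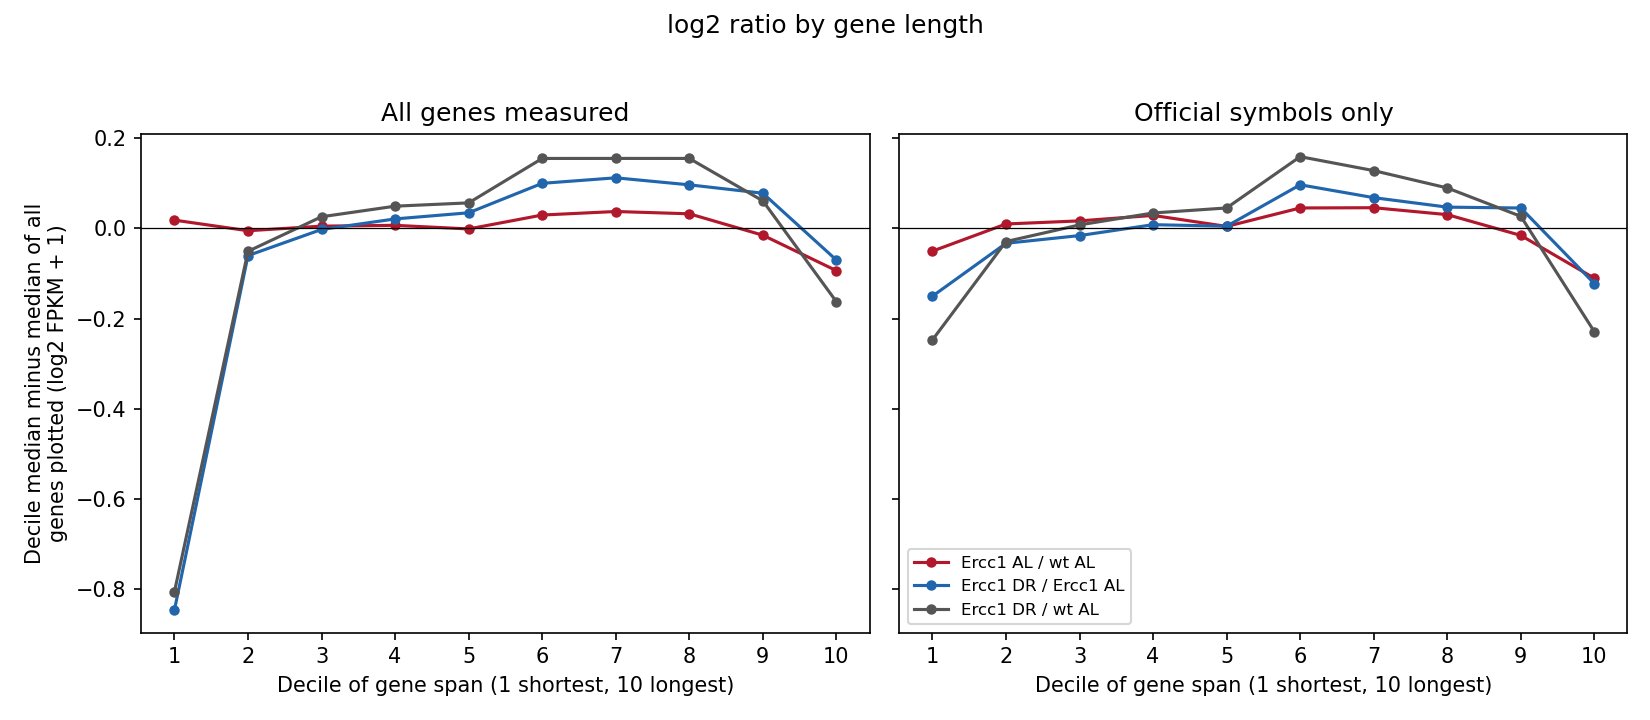
Median log2 ratio of genes in each decile of gene span minus the median of all genes plotted (y axis), against the decile (x axis), for the 3 comparisons, with all measured genes on the left and official symbols on the right. With official symbols the longest decile lies 0.11, 0.12 and 0.23 below the median of all genes in the 3 comparisons. Mean expression is also lowest in that decile, so length and level are not separated.

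For each gene the library that stood apart was recorded. This bears only in part on whether diet in the mutant moved genes back toward the wild type. The genes were chosen on their range over all 3 libraries and include those that differ only in Ercc1 DR. A low share for Ercc1 AL thus does not tell whether genes that differ between genotypes moved back. Among 4545 genes with at least a 2-fold range, Ercc1 DR stood apart for 58.6% (exact binomial 95% interval 57.2 to 60.1), wt AL for 31.5% (30.2 to 32.9) and Ercc1 AL for 9.88% (9.03 to 10.8), against 33.3% each if no library differed more than another. After rescaling the shares were 60.3%, 30.6% and 9.07%, and with official symbols only the share of Ercc1 AL was 5.18%. Cyp7b1 and Scd1 were among the genes for which Ercc1 AL stood apart, as deposited and after rescaling. Genotype and diet log2 ratios share the Ercc1 AL library, which gives a Pearson's r of -0.50 across genes for unrelated libraries of equal spread. The observed r was -0.07 over 11189 genes. After each ratio was centred on its median, signs were opposite in 42.7% of genes, against 66.6% for such libraries. Genotype log2 ratios and those of Ercc1 DR against wt AL share the wt AL library. They had an r of 0.55, against 0.50 for unrelated libraries of equal spread. The spread of log2 ratios across genes was not equal here. It was smallest for Ercc1 AL against wt AL and largest for Ercc1 DR against wt AL. Unrelated libraries of unequal spread give other values, so these gaps cannot tell whether diet moved genes back. Genes are not independent replicates, and part of either r comes from the shared library.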

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

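Each group has 1 library, so settings describe how the processing moves a value and say nothing of animals. No paired analysis was possible because each group has a single library. The midpoint of the interval and official symbols with median rescaling were added after the data were examined, and the cause of the shifts below was not tested. All 60 values of the 20 leading genes per comparison kept their sign in 596 alternatives. These genes were chosen for the largest ratios, so a change of sign was hardly possible.

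Counts of genes at least 2-fold higher and lower follow in the order Ercc1 AL against wt AL, Ercc1 DR against Ercc1 AL and Ercc1 DR against wt AL. They were 717 and 272, 803 and 1077, and 2916 and 1047 in the text. With a pseudocount of 0.1 they were 1575 and 514, 1218 and 1886, and 4425 and 1647. With a pseudocount of 5 they were 370 and 95, 386 and 628, and 1173 and 547. Rescaled to a median log2 ratio of 0 they were 291 and 605, 386 and 1479, and 730 and 1997. Rescaled to the upper quartile they were 320 and 556, 448 and 1368, and 927 and 1822. Scaled to the sum without the 100 most abundant genes, which still includes most small RNA genes, they were 207 and 877, 6367 and 209, and 4946 and 686. With official symbols they were 386 and 186, 736 and 489, and 2660 and 627. At 1.5-fold they were 2942 and 684, 2661 and 2052, and 5463 and 1814. At 4-fold they were 135 and 39, 94 and 271, and 357 and 288.

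Spearman's rho of gene length for Ercc1 AL against wt AL was -0.0338 with a pseudocount of 0.1, -0.0934 with 5, 0.0671 with no filter on low values (the opposite sign), -0.0791 at an FPKM of at least 5, -0.0312 after median rescaling, -0.0356 after upper quartile rescaling, -0.0114 after scaling without the 100 most abundant genes, -0.0391 with official symbols, -0.0390 with genes of at least 1 kb, -0.0213 as a partial rho given expression, -0.0329 with interval midpoints and -0.0198 with official symbols and median rescaling. For Ercc1 DR against Ercc1 AL it was 0.121 with no filter, 0.284 at an FPKM of at least 5, 0.115 without the 100 most abundant genes, 0.0336 with official symbols, 0.177 with exonic length, 0.0328 with genes of at least 1 kb, 0.218 as a partial rho, 0.136 with midpoints and 0.0441 with official symbols and median rescaling. For Ercc1 DR against wt AL it was 0.124 with no filter, 0.201 at an FPKM of at least 5, 0.124 after median and 0.120 after upper quartile rescaling, 0.0110 with official symbols, 0.00459 with genes of at least 1 kb, 0.166 as a partial rho and 0.0324 with official symbols and median rescaling.

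The share of genes for which Ercc1 AL stood apart, 9.88% in the text, was 13.4% with a pseudocount of 5, 6.13% without the 100 most abundant genes, 5.18% with official symbols, 14.5% at a 4-fold range, 11.2% at a 1.5-fold range, 8.32% with midpoints and 5.53% with official symbols and median rescaling. In 99 tests of the lists fixed beforehand, 41 medians stood apart, and 26 did at an FPKM of at least 5, where fewer lists had enough measured members. The added lists are outside these counts. Lists that stood apart and lost that in 1 setting were erythroid, endothelial and cholangiocyte markers in Ercc1 AL against wt AL, macrophage, endothelial and pancreatic markers, the unfolded protein response and gluconeogenesis in Ercc1 DR against Ercc1 AL, and the circadian clock and gluconeogenesis in Ercc1 DR against wt AL. Lists that did not stand apart but did in 1 or 2 settings were the growth hormone and IGF1 axis, bile acids and the unfolded protein response in Ercc1 AL against wt AL, histones and senescence in Ercc1 DR against Ercc1 AL, and p53 targets, the growth hormone and IGF1 axis, autophagy, the unfolded protein response and cholangiocyte markers in Ercc1 DR against wt AL. The interferon response list in Ercc1 AL against wt AL turned to 0.31 at an FPKM of at least 5, and the cell cycle list in Ercc1 DR against Ercc1 AL to 0.068 with no filter.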

Other observations

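The tests on background over silent receptor genes and its size, on female animals, on major urinary protein genes and on small RNA shares were chosen after the result was seen, and those on small RNA genes in exons and on short transcripts before. For the size of the background, the limit on the share of genes within the receptor genes' drop was first set lower. It was raised to a majority of the genes after the value was seen. The interval of 13.7 to 20.5% reaches past the first limit. Some genes were nearly silent under free feeding, and others were ordered over all 3 libraries. Lepr and Sult1e1 had less than 2 FPKM in both freely fed libraries and 53.03 and 30.1 FPKM in Ercc1 DR. Csn1s2a was at 43.0, 2.96 and 0.563 FPKM in wt AL, Ercc1 AL and Ercc1 DR, and Gpcpd1 at 2.88, 16.2 and 77.3 FPKM, in single libraries.

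A first pattern is the 489 official symbols at least 2-fold lower in Ercc1 DR than in Ercc1 AL, of which the 486 with an exonic length in the reference were tested. They include the endothelial markers Oit3 and Gpr182. The size of their drop was set against that over receptor genes. Of these genes 16.9% had a drop within the 99th percentile of that of receptor genes (2.55 FPKM). The median drop was 5.74 FPKM, against 0.0884 FPKM in receptor genes. The choice by a 2-fold drop itself forces large drops, as the genes' median in Ercc1 AL was 8.48 FPKM. A gene at 5 FPKM or more in Ercc1 AL could not lie within 2.55 FPKM. Only 138 of the 486 (28.4%) were under 5 FPKM. A majority within that drop was thus out of reach, so the share does not decide whether lost background reads were the cause. A larger background was not tested. Receptor genes were 20 of the 486, a larger share than among other genes. With these, 34 belonged to receptor, keratin, skin barrier, beta-defensin and milk casein families. One of them, Lce3a, fell from 128 to 9.72 FPKM. For the 82 genes with a drop within 2.55 FPKM, a lower background could be the cause as a hypothesis. The silent receptor genes had a median log2 FPKM ratio of -1.001. Small RNA genes lay in the exons of 1.85% of them, and 8.02% had exons shorter than 1 kb against 2.85% of other genes, so neither accounts for more than a small part, and a change in cell composition was not tested.

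A second pattern is that male-biased genes were lower and female-biased genes higher in Ercc1 DR than in Ercc1 AL. A larger share of female animals would lower Y-linked genes and raise Xist, but the median log2 ratio of Y-linked genes was 0.48 and that of Xist -0.37, as deposited, the opposite of both. The Y-linked genes differed among themselves. After rescaling Eif2s3y, Ddx3y and Uty were at 0.78, 0.41 and 0.06, and Kdm5d was at -0.45. Xist was low throughout, at 0.646, 0.857 and 0.437 FPKM in wt AL, Ercc1 AL and Ercc1 DR. Shared reads among major urinary protein genes do not account for it either, since the male-biased list without them had a median of -2.21 relative to matched lists. A hypothesis that remains is an altered pattern of growth hormone secretion under diet restriction, which might be tested by hormone sampling and was not tested here. The growth hormone and IGF1 axis list itself did not stand apart (0.17). Of its 13 members 2 were at least 2-fold higher and 2 lower, so its median does not bear on this hypothesis.

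The last pattern is that the median log2 ratio was above 0 in all 3 comparisons, in Ercc1 DR against wt AL at 0.50 over the measured genes and 0.78 over the 9109 genes with at least 1 FPKM in all libraries. A smaller share of fragments from small RNA genes could raise all other genes. Small RNA genes made up 33.9%, 28.9% and 18.6% of the implied fragments in wt AL, Ercc1 AL and Ercc1 DR. These shares were estimated from the widths of the deposited intervals, over rows with an estimate, and were not counted. The shares left for other genes gave a log2 ratio of 0.30 in Ercc1 DR against wt AL, beside the shift of 0.78. In Ercc1 AL against wt AL the ratio was 0.10 beside a shift of 0.49, and in Ercc1 DR against Ercc1 AL 0.20 beside 0.33. A smaller share of small RNA cannot be told apart from a change in the most abundant transcripts, because those rows hold no estimate. Counts per library with all transcripts would bear on it.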
